A study of Mus musculus with 15 samples.

How the data were processed

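Polyadenylated RNA of EpCAM-enriched tumour cells was sequenced from 15 libraries, 8 of tumours grown in control mice and 7 of tumours grown in obese mice, each taken 4 weeks after organoid transplant. The deposited table gave the raw count of reads per gene for each library, in the layout of STAR's gene count output. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17, reads were trimmed with Trimmomatic and aligned to GRCm38 with STAR. The annotation release and the strand column taken from STAR are not given in the sources used here, so counts of genes that overlap another gene, on either strand, are uncertain. The table held 55475 lines, of which 4 were summary lines of unmapped, multimapping, unassigned and ambiguous reads and 55471 were genes. All 15 value columns were assigned to a library by name. The summary lines held on average 6.71%, 3.61%, 5.41% and 6.59% of the reads of a library and were kept out of library sizes. Gene identifiers were given symbols from a reference table, which held 54487 of them at the same version and 55144 in all, and coordinates come from GENCODE release M 21 on GRCm38. A symbol carried by several identifiers was assigned to the one with most counts.

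Groups were taken from the sample titles and treatment labels. The labels state neither the sex of the mice nor any pairing, and do not say outright that each library is a separate animal, so p-values measure the spread between these libraries. Gene counts per library ranged from 19206205 to 29415264. The common biological coefficient of variation was 25.1%, so the spread between libraries, and for scarce transcripts the count itself, limited precision.

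Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total 15), which left 15750, and libraries were scaled by TMM. Dispersions were estimated with estimateDisp and tested by glmQLFit with robust estimation and glmQLFTest, two-sided, for obese minus control with no other term. p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of adjusted p under 0.05 and no minimum fold. The SE of a log2 fold change was derived from the quasi-likelihood F statistic. Group means are CPM after TMM scaling, and log2 CPM used a prior count of 2.

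Gene lists, 45 in number, were written from textbook knowledge before the data were examined, as were the tests, the rule for naming genes and the alternatives except where stated. The inflammatory lists were NF-kB and TNF response, interferon response, MHC class I presentation, MHC class II presentation, the IL-6, STAT3 and acute phase list, and epithelial alarm and antimicrobial genes. The metabolic lists were fatty acid oxidation and PPAR targets, fatty acid synthesis, cholesterol synthesis, glycolysis, the nuclear-encoded respiratory chain, the tricarboxylic acid cycle, serine, one-carbon and nucleotide synthesis, glutathione and xenobiotic metabolism, and insulin and IGF signalling. The proliferation lists were E2F and DNA replication, mitosis and G2/M, MYC targets and ribosome biogenesis, and cytosolic ribosomal proteins. Lists of epithelial state covered intestinal stem cell and Wnt targets, a fetal-like and YAP programme, epithelial-mesenchymal transition, absorptive colonocytes, goblet and deep crypt secretory cells, enteroendocrine cells and tuft cells. Lists of stress and RNA quality covered hypoxia, the unfolded protein response, dissociation and immediate early genes, mitochondrially encoded transcripts and p53 targets. Lists of other cell types covered T and NK cells, B and plasma cells, macrophages and dendritic cells, neutrophils, fibroblasts, endothelial cells, smooth muscle and pericytes, adipocytes, enteric glia and neurons, mesothelium and red blood cells. The last 3 lists, engineered loci, sorting markers with epithelial keratins, and sex-linked genes, were read as values and not tested as sets. Lists with at least 3 members past the filter were tested as sets, which left 41.

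Each list was tested with camera of limma 3.58.1 on the edgeR fit with a preset inter-gene correlation of 0.01, beside camera with the correlation estimated per list and fry, directional and mixed. The score of a list, its members' mean log2 CPM per library, was compared between groups by an exact two-sided permutation test over all 6435 divisions of the libraries, whose smallest possible p is 1.55e-04, and adjusted over the 41 lists. Counts of members past the threshold are given over all genes and adjusted over the list alone. Correlations across libraries used 100000 permutations, or every ordering within a group. The text names the 12 genes in each direction of smallest p with a mean log2 CPM of at least 1, the 5 of smallest p in each direction, up to 4 members of smallest p from each list that camera called, and every gene of the 3 lists read as values. Unnamed gene models, immunoglobulin and T cell receptor segments and pseudogenes were left out of the first of these. The rule would have ranked by fold change among genes past the threshold, but fewer than 10 passed. Further list members are named where a sentence contrasts them.

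Alternatives were DESeq2 size factors, library size alone, no gene filter, a filter at a mean of 10 CPM, DESeq2 1.42.0 (917 genes without an adjusted p by its own filter, and outlying counts replaced by its default), limma-voom with quality weights, no robust estimation, the run of EG numbers as a term and each run alone, the score of other cell types as a term, 1 surrogate variable from sva 3.50.0, each library left out in turn, list members of no other list, and scores from z values or medians. Chosen after the data were seen were leaving out EG189 and EG251 together and an offset for each library's trend on transcript length and GC content. That trend was fitted over genes with a mean log2 CPM above 1, with natural splines of 4 degrees of freedom each on the log2 length and the GC content of the longest annotated transcript, and camera then ran on the corrected log2 values. A library's trend on length is given as the Spearman correlation, across 10079 genes with a mean log2 CPM above 3, of transcript length with the gene's log2 CPM minus its mean over libraries.

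The procedure was tested on simulated counts with the means, dispersions and library sizes of these genes. Of 50 genes changed at each size, 28% at the smallest size (a factor of 5/4), 68% at 1.5-fold, 90% at 2-fold and 96% at 3-fold were called in the right direction, so most genes changed by the smallest size were missed, and 13 of 165 calls fell on unchanged genes. The changed genes were drawn from those with a mean above 2 CPM, so recovery of scarcer genes was not tested. An adjusted p also depends on how many genes change, and the simulation gave 165 calls. Its rates may therefore overstate recovery where fewer genes change or where genes vary together. Of 40 lists of unchanged genes 0 were called by camera or by the score test, in a simulation whose genes vary independently of each other. No data were left out of the main comparison. Figures were drawn in Python 3.11.15.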

Results

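The series measured RNA from epithelial tumour cells taken out of the mouse colon. Organoids without Apc, Trp53 and Smad4, carrying the Kras G12D allele and the red fluorescent protein tdTomato, had grown for 4 weeks beneath the colonic mucosa of control or obese C57BL/6 mice. The tumours were dissociated, cells bearing the leukocyte antigen CD45 were removed on magnetic beads, and cells bearing the epithelial adhesion molecule EpCAM were then enriched. The data held 15 libraries, 8 from control and 7 from obese hosts. How obesity was brought about was not stated. Gene counts per library ranged from 19206205 to 29415264, with a mean of 26295208 ± 1947826 in control libraries (SD, n = 8) and 22835576 ± 2632126 in obese libraries (SD, n = 7). At this depth a transcript at 1 CPM (counts scaled to a common library total) rested on 19.2 to 29.4 counts. The 15 libraries are named below by their EG numbers.

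The cells were epithelial in both groups. Epcam was read at 1643 ± 91.1 CPM in control libraries (SD, n = 8) and 1753 ± 123 CPM in obese libraries (SD, n = 7). The simple-epithelium keratins Krt8, Krt18 and Krt19 lay at or above 1602 CPM in every library, and Cdh1, the adherens junction cadherin, lay between 1451 and 2487 CPM. Krt20, Vil1 and Cdx2, genes of intestinal identity and differentiation, averaged 34.3, 381 and 20.8 CPM in control libraries and 30.8, 392 and 19.9 CPM in obese libraries. The engineered loci still gave counts. Apc lay between 91.6 and 194 CPM, Trp53 between 9.45 and 29.0 CPM, Smad4 between 91.4 and 132 CPM and Kras between 104 and 147 CPM, and since the deleted exons are not given these values do not test the genotype. Xist, the transcript of the inactive X chromosome, lay between 324 and 749 CPM in all libraries, while the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y gave at most 7 counts. Ptprc, which encodes CD45, averaged 9.66 ± 2.86 CPM in control libraries (SD, n = 8) and 24.1 ± 29.8 CPM in obese libraries (SD, n = 7). The obese library EG189 alone reached 90.8 CPM of Ptprc, against at most 20.7 CPM in the other 14 libraries.

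The series asked whether host obesity alters the inflammatory, metabolic and proliferative transcripts of these tumours. The gene of smallest p was Msmo1, a sterol methyl oxidase of cholesterol synthesis (gene ENSMUSG00000031604.10, chromosome 8, 64718139 to 64733792, GRCm38). It averaged 83.6 ± 7.60 CPM in control libraries (SD, n = 8) and 113 ± 10.8 CPM in obese libraries (SD, n = 7), a log2 fold change of 0.43 ± 0.07 (SE) with an edgeR adjusted p of 0.181. Sc5d, Cyp51 and Pmvk, enzymes of the same pathway, were also among the 12 higher genes of smallest p, at 1.27, 1.35 and 1.22 times the control level. The other higher genes of that rank were Acot7 (1.29-fold), an acyl-CoA thioesterase, Prss12 (1.40-fold), a serine protease, Mab21l3 (3.01-fold), Mrpl45 (1.24-fold), a mitochondrial ribosomal protein, and Antxr2 (1.29-fold), a receptor of anthrax toxin. Tnfrsf11b (1.28-fold), the decoy receptor osteoprotegerin, Ran (1.23-fold), the GTPase of nuclear transport, and Lgals1 (1.54-fold), which encodes a galectin, completed them. The 12 lower genes of smallest p were Dop1b (0.769 of the control level), Vwa5a (0.807), Boc (0.644), a hedgehog co-receptor, Akap8l (0.788), Ephb6 (0.713), an Eph receptor without kinase activity, and Cplx2 (0.608), a complexin. The rest were Uhrf1bp1 (0.800), Gabbr1 (0.762), a subunit of the GABA-B receptor, Cuedc1 (0.818), Capn15 (0.784), Cd200r2 (0.660) and Snx22 (0.619), a sorting nexin.

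All 7 obese libraries lay on the same side of the control median for each of these 24 genes, except Gabbr1, for which 1 obese library lay above it. Since the genes were chosen by their p in these libraries, that count was favoured by the choice. None of the 24 passed the threshold. Of 15750 genes tested, edgeR called 0 higher and 0 lower at adjusted p under 0.05, the smallest adjusted p after that of Msmo1 being 0.318. At unadjusted p under 0.05 there were 1822 genes, 1019 higher and 803 lower, where 787.5 would be expected by chance. limma-voom also called 0 genes, while DESeq2 called 26, of which 18 were higher and 8 lower. These included 19 of the 24 genes above. They also included, chosen after their values were seen, Cxcl3, a neutrophil-attracting chemokine (1.98-fold in DESeq2 and 3.73-fold in edgeR), Il1f9, an interleukin of the IL-1 family, and Pglyrp1, a peptidoglycan recognition protein, for all of which EG189 held the highest value. Of the 19, EG189 also held the highest value of Sc5d, Acot7, Mab21l3, Mrpl45, Ran and Lgals1, and the lowest of Dop1b, Vwa5a and Ephb6. It held neither extreme for Msmo1, Prss12, Boc, Akap8l, Cyp51, Pmvk, Tnfrsf11b, Cplx2, Antxr2 and Cd200r2. Without control library EG235 edgeR called 1 gene, Acot7, and without obese library EG250 it called 1 gene, Plch2.

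Cholesterol synthesis had the smallest camera p of the lists. All 22 of its members had a positive log2 fold change, with a median of 1.19-fold, and 12 were higher when adjusted over the list alone, against 0 over all genes. Beyond Msmo1, Sc5d, Cyp51 and Pmvk these included Insig1, which retains the sterol sensor in the endoplasmic reticulum, and Hmgcr, the rate-limiting reductase, at log2 fold changes of 0.37 ± 0.09 and 0.25 ± 0.09 (SE). The list score, the mean log2 CPM of its members, was 6.01 ± 0.13 in control libraries (SD, n = 8) and 6.25 ± 0.20 in obese libraries (SD, n = 7), a difference of 0.24 with an exact permutation p of 0.0208. It lay above the control median in 6 of 7 obese libraries. Adjusted over the 41 lists that p became 0.142. camera with a preset correlation called the list at adjusted p = 1.11e-15, and with an estimated correlation its adjusted p = 0.306. Without library EG189 13 members passed over the list alone, and with transcript length and GC content offset 13 did so.

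**Figure D1:**
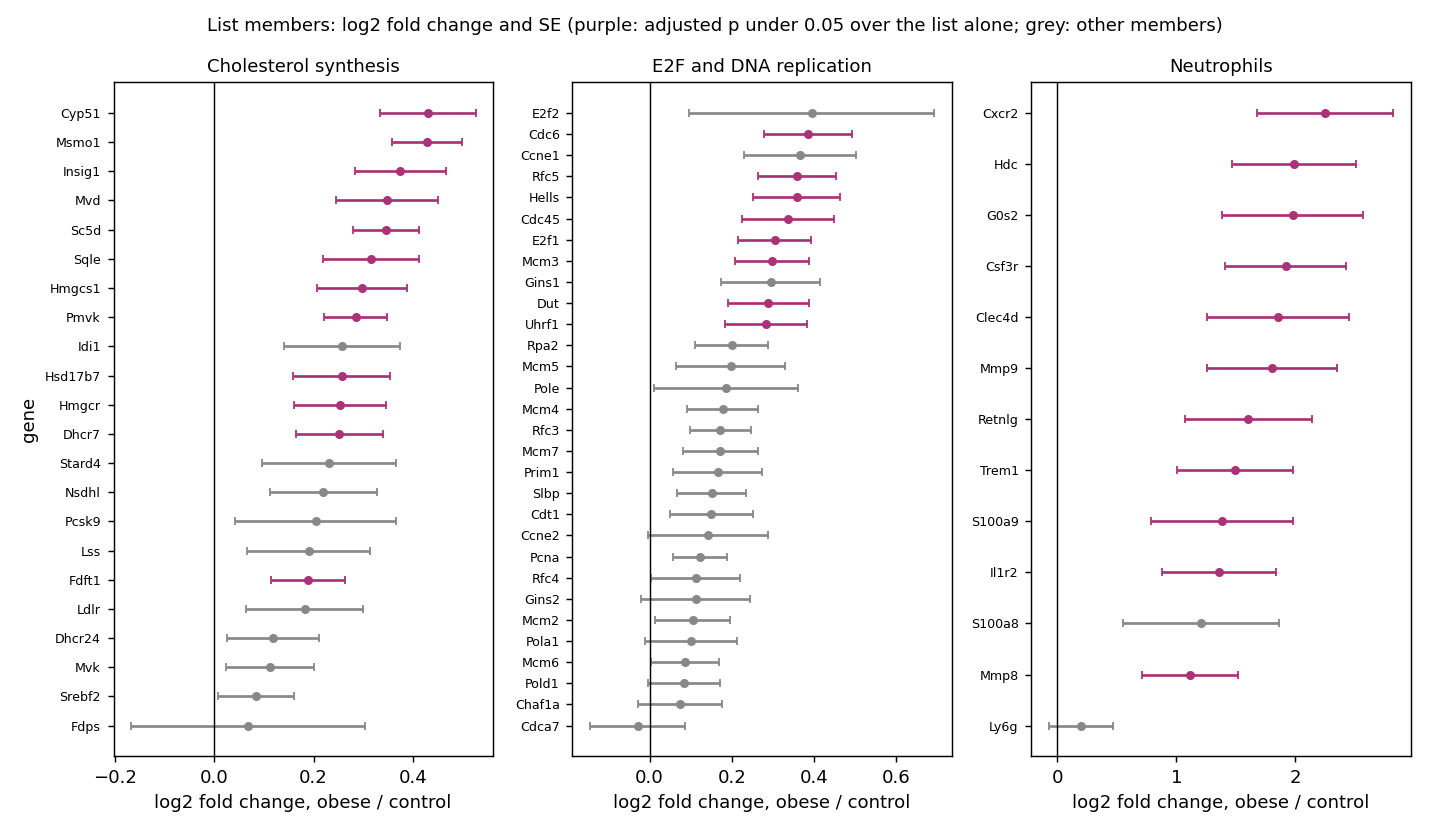
Log2 fold change (obese over control, horizontal axis, log2 units) with its SE for each tested member of 3 gene lists, from 8 control and 7 obese libraries. Purple marks the 12 cholesterol synthesis, 8 DNA replication and 11 neutrophil genes past the threshold when adjusted over the list alone, and all 22 cholesterol genes lie right of 0.

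Enzymes of fatty acid elongation and lipid storage differed at single genes. In the fatty acid synthesis list 14 of 20 members were positive, and Elovl6, a fatty acid elongase (1.37-fold), and Dgat2, which makes triglycerides (1.37-fold), were higher when adjusted over the list alone, against 0 over all genes. Gpam, a glycerol phosphate acyltransferase, stood at 0.841 and Me1, malic enzyme, at 1.30 of the control level, and neither passed. In the list of fatty acid oxidation and PPAR targets 24 of 27 members were positive, and 1, Pdk4, the kinase that restrains pyruvate dehydrogenase, was higher over the list alone (4.86 ± 1.57 CPM in controls, SD, n = 8, and 9.29 ± 2.93 CPM in obese, SD, n = 7). Plin2, a lipid droplet coat protein, was at 1.29-fold without passing. camera called both lists as higher, at adjusted p = 0.0181 for synthesis and 0.00150 for oxidation, and for both the adjusted p = 0.529 with an estimated correlation. Without EG189 only 1 member of the synthesis list passed over the list alone, although its median was 1.07-fold, as with all libraries, and 15 of 20 members were positive. Without EG195 camera did not call that list (adjusted p = 0.211). Their scores differed by 0.11 and 0.15, with exact permutation p of 0.114 and 0.263. The score difference of the oxidation list was 0.34 in libraries EG164 to EG195 and -0.01 in libraries EG226 to EG251.

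Serine, one-carbon and nucleotide synthesis had 20 of 24 members positive and 5 higher over the list alone, against 0 over all genes. These 5 were Phgdh, the first enzyme of serine synthesis (1.23-fold), Tyms, thymidylate synthase (1.26-fold), Rrm2, a subunit of ribonucleotide reductase (1.36-fold), Slc7a11, the cystine transporter (1.42-fold), and Asns, asparagine synthetase (1.18-fold). The score was higher than the control median in all 7 obese libraries, with a difference of 0.17 and an exact permutation p of 0.00839, which became 0.142 over all lists. camera gave adjusted p = 1.00e-06 with a preset correlation and adjusted p = 0.306 with an estimated correlation. Without EG189 0 of its members passed in edgeR over the list alone, although 11 had an unadjusted p under 0.05, as 11 did with all libraries, and the median was 1.13-fold without EG189 against 1.12-fold with it.

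The nuclear-encoded respiratory chain had 31 of 32 members positive at a median of 1.10-fold, and 0 passed in edgeR over the list alone (3 at unadjusted p under 0.05). Uqcrfs1 and Cox5a, subunits of complexes III and IV, had log2 fold changes of 0.22 ± 0.07 and 0.33 ± 0.12 (SE). Its score difference was 0.14, with an exact permutation p of 0.121. This score followed transcript length across libraries: it correlated with each library's trend of expression on length at r = -0.94 over 15 libraries (permutation p = 1e-05, the smallest that 100000 permutations can give, and 4e-05 adjusted over 4 relations), rho = -0.95 (permutation p = 1e-05), and r = -0.94 without EG189 and EG239. Within the 8 control libraries r was -0.98 (exact permutation p = 7.44e-05) and within the 7 obese libraries -0.89 (exact permutation p = 0.0107). Any list of mostly short or mostly long transcripts would follow such a trend, so these r do not point to its cause. After that trend was removed the difference was 0.10 (exact permutation p = 0.0614). Glycolysis had 15 of 17 members positive, with Ldha, Eno1 and Gapdh at 1.16-fold, 1.15-fold and 1.16-fold, and 0 past the threshold in edgeR over the list alone (3 at unadjusted p under 0.05). The tricarboxylic acid cycle had 19 of 22 members positive, and 1, Mdh2, malate dehydrogenase (1.16-fold), was higher over the list alone. Glutathione and xenobiotic metabolism had 16 of 19 members positive, and 1, Gsr, glutathione reductase (1.27-fold), was higher over the list alone (0 without EG189), while Aldh1a1 was at 0.656 of the control level without passing. Without EG189 the median of this list was 1.11-fold, against 1.15-fold with all libraries. camera called these 4 lists as higher with a preset correlation, at adjusted p of 3.64e-07, 0.00335, 0.0144 and 0.0181 in that order, and for each the adjusted p = 0.529 with an estimated correlation. With length and GC offset the cycle and the glutathione list were no longer called (adjusted p of 0.153 and 0.102), although the median of the glutathione list stayed near its level (1.13-fold against 1.15-fold, 16 of 19 positive in both), while that of the cycle was 1.02-fold against 1.04-fold with 15 of 22 positive. Leaving out 1 library also ended the call of glycolysis (without EG235 or EG251, adjusted p up to 0.0698) and of the cycle (without EG175, EG186 or EG250, up to 0.0851). The call of the glutathione list ended without EG175, EG229, EG189 or EG250 (up to 0.0933). Insulin and IGF signalling had 13 of 20 members negative and was not called (camera adjusted p = 0.0930).

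Genes of DNA replication had mostly positive fold changes in the obese group. Of 30 members of the E2F and DNA replication list 29 had a positive log2 fold change, with a median of 1.13-fold, and 8 were higher over the list alone, against 0 over all genes. Among these 8 were Rfc5, a clamp loader subunit (1.28-fold), Cdc6, a licensing factor (1.31-fold), E2f1, the transcription factor that drives such genes (1.24-fold), and Hells, a chromatin remodeller (1.28-fold). The score was 4.89 ± 0.15 in control libraries (SD, n = 8) and 5.09 ± 0.14 in obese libraries (SD, n = 7), and it exceeded the control median in all 7 obese libraries. The difference of 0.20 had an exact permutation p of 0.0168, which became 0.142 over the 41 lists. camera gave adjusted p = 1.20e-10 with a preset correlation and adjusted p = 0.306 with an estimated correlation. Without EG189 5 members passed over the list alone.

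Mitosis and G2/M genes had 29 of 30 members positive at a median of 1.15-fold, with Cdk1 and Bub1 at 1.22-fold and 1.27-fold, but 0 passed in edgeR over the list alone and 1 had an unadjusted p under 0.05. The score difference of 0.19 lay within the spread between libraries (exact permutation p = 0.252, 3 of 7 obese libraries above the control median). camera called it at adjusted p = 2.49e-05, against adjusted p = 0.545 with an estimated correlation. MYC targets with ribosome biogenesis genes and cytosolic ribosomal proteins had medians of 1.02-fold and 1.02-fold and were not called (camera adjusted p of 0.575 and 0.456). Without EG189 the ribosomal proteins had the opposite direction, at a median of 0.991 with 11 of 28 members positive. Their direction was also opposite without EG229, EG186 or EG239.

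Transcripts of the NF-kB and TNF response had mostly positive fold changes in the obese group. Of 24 members 21 were positive, and 5 were higher over the list alone, against 0 over all genes. These were Cxcl5 and Cxcl2, chemokines that attract neutrophils (2.28-fold and 2.16-fold), Il1b, the cytokine interleukin-1 beta (3.54-fold), Tnfaip2 (1.79-fold) and Zc3h12a, an endonuclease that cleaves cytokine transcripts (1.26-fold). Cxcl5 averaged 59.6 ± 30.9 CPM in control libraries (SD, n = 8) and 136 ± 50.03 CPM in obese libraries (SD, n = 7), and all 7 obese libraries lay above the control median. The score difference was 0.36, with an exact permutation p of 0.0127 that became 0.142 over the 41 lists, and 6 of 7 obese libraries lay above the control median. camera gave adjusted p = 4.09e-08 with a preset correlation and adjusted p = 0.306 with an estimated correlation. EG189 had the highest score of this list, and without it 0 members passed in edgeR over the list alone (6 at unadjusted p under 0.05) and Il1b stood at 1.68-fold. The score difference without it was 0.28 (exact permutation p = 0.0330), and camera called the list in all 15 fits without 1 library. In EG189 Il1b stood at 334 CPM, against a mean of 29.2 CPM in the other 14 libraries, beside leukocyte transcripts such as Lyz2 (1282 against 126 CPM) and Csf3r (40.2 against 3.67 CPM). With 1 library left out at a time the log2 fold change of Tnfaip2 went from 0.84 to as low as 0.47. That of Cxcl5 went from 1.19 to no lower than 0.9955.

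Epithelial alarm and antimicrobial genes had 16 of 17 members positive. Lcn2, the siderophore-binding lipocalin, averaged 37.3 ± 15.6 CPM in control libraries (SD, n = 8) and 72.3 ± 17.9 CPM in obese libraries (SD, n = 7), and Duoxa2, the maturation factor of a hydrogen peroxide-producing oxidase, was at 1.70-fold. In edgeR 0 members passed over the list alone and 4 had an unadjusted p under 0.05. All 7 obese libraries scored above the control median, with a difference of 0.42 (exact permutation p = 0.0402, 0.214 over all lists). camera gave adjusted p = 7.64e-05 with a preset correlation and adjusted p = 0.306 with an estimated correlation. EG189 had the highest score of this list too, which shares S100a8 and S100a9 with the neutrophil list. Without it the score difference was 0.32 (exact permutation p = 0.0912), 2 members had an unadjusted p under 0.05, Lcn2 stood at 1.87-fold and S100a9 at 1.38-fold. The IL-6, STAT3 and acute phase list had 15 of 18 members positive and lay just above the threshold (camera adjusted p = 0.0511). It was called in 6 of 15 fits without 1 library (EG164, EG167, EG226, EG227, EG195 or EG239), the adjusted p ranging from 0.00738 to 0.137, against adjusted p = 0.529 with an estimated correlation and all libraries. Interferon response genes had 27 of 30 members negative at a median of 0.909 of the control level, and were not called with all libraries (camera adjusted p = 0.0977, score exact permutation p = 0.786). This rested on single libraries, since camera called them as lower in 6 of 15 fits, without EG164, EG171, EG229, EG186, EG189 or EG251, and the adjusted p ranged from 5.99e-05 to 0.857. The direction was opposite without EG235, and without EG189 and EG251 together 30 of 30 members were negative (adjusted p = 3.24e-05). These calls used the preset correlation, whereas the estimated correlation of this list was 0.794 and gave adjusted p = 0.807 with all libraries. MHC class I and class II presentation had 9 of 16 and 6 of 8 members positive and were not called (camera adjusted p of 0.737 and 0.494). Without EG189 both had the opposite direction, with 4 of 16 and 1 of 8 members positive and medians of 0.942 and 0.846 of the control level. This was not particular to EG189. The direction of class I was also opposite without EG164, EG171, EG229 or EG251, and that of class II without EG164 or EG229.

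**Figure D2:**
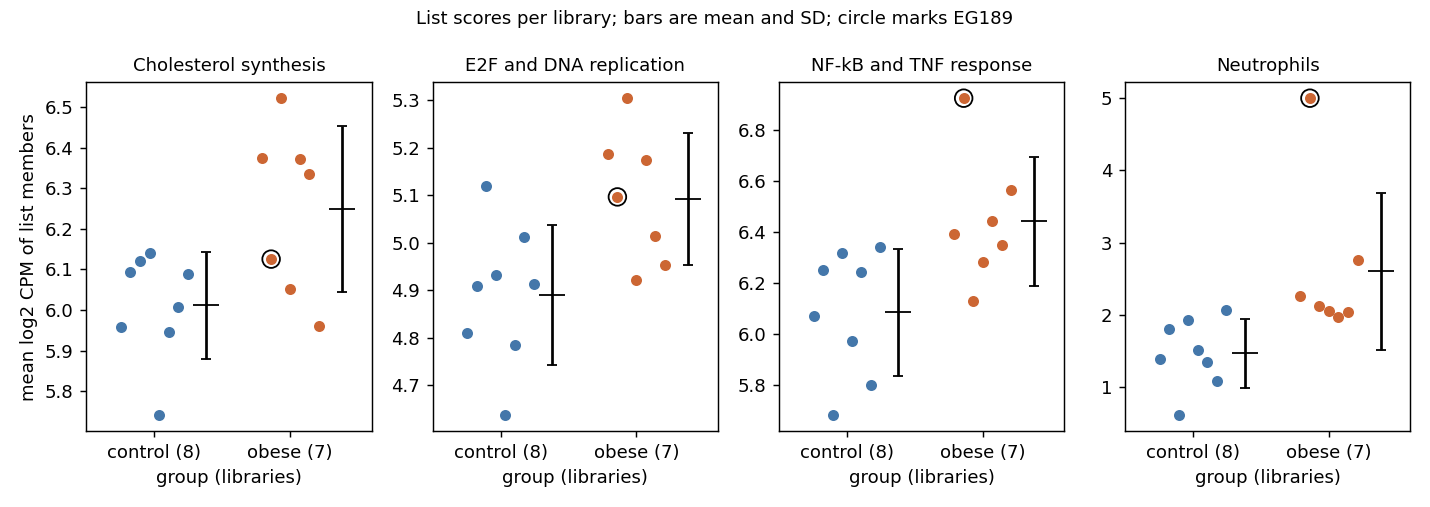
Score of 4 gene lists (vertical axis, mean log2 CPM of the members) in each of 8 control and 7 obese libraries, with the mean and SD of each group beside the points and a circle around library EG189. The obese means exceed the control means by 0.24, 0.20, 0.36 and 1.14 from left to right.

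Neutrophil transcripts had positive fold changes, and their score passed over the lists with all 15 libraries. The score of the neutrophil list was 1.46 ± 0.48 in control libraries (SD, n = 8) and 2.60 ± 1.09 in obese libraries (SD, n = 7), a difference of 1.14 with an exact permutation p of 9.32e-04 and an adjusted p of 0.0382, and all 7 obese libraries lay above the control median. It was the only one of the 41 lists whose score passed, and it did not pass with the run of EG numbers as a term (difference 1.17, adjusted p = 0.0669) or with z values (adjusted p = 0.0765). All 13 members were positive, and 11 were higher over the list alone, against 0 over all genes. Cxcr2, a receptor for neutrophil-attracting chemokines, was at 4.76-fold, Csf3r, the receptor of granulocyte colony-stimulating factor, at 3.78-fold, Hdc, which makes histamine, at 3.96-fold and Mmp9, a gelatinase, at 3.49-fold. S100a8, a calprotectin subunit, and Ly6g did not pass over the list alone. These transcripts were scarce, Cxcr2 averaging 0.746 CPM in control and 3.58 CPM in obese libraries. camera gave adjusted p = 8.38e-10 with a preset correlation and adjusted p = 0.306 with an estimated correlation.

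Library EG189 held a large part of that difference. Without it the score difference was 0.74 (exact permutation p = 0.00400, adjusted p = 0.168), Cxcr2, Csf3r, Hdc and Mmp9 stood at 2.20-fold, 1.89-fold, 2.16-fold and 1.71-fold, and 6 members passed over the list alone. With 1 library left out at a time the call held without EG235 or without EG243 and was lost in the other 13 fits, the adjusted p ranging from 0.0239 to 0.168 and the unadjusted exact p from 5.83e-04 to 0.00400.

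Other cells of the tumour gave mixed values. B and plasma cell genes had all 14 members positive, 7 of them higher over the list alone, with Igha and Igkc, immunoglobulin chains, at 6.58-fold and 5.83-fold, and camera called the list (adjusted p = 7.40e-04, against adjusted p = 0.529 with an estimated correlation). EG189 held most of that signal, since its Igha stood at 1639 CPM against at most 86.0 CPM elsewhere. Without it camera gave adjusted p = 0.367, 9 of 14 members were positive and Igha and Igkc were at 1.26-fold and 1.19-fold. Macrophage and dendritic cell genes had all 18 members positive, with Itgax and Itgam at 2.51-fold and 2.40-fold, 0 past the threshold in edgeR over the list alone (5 at unadjusted p under 0.05), and camera adjusted p = 9.05e-05, against adjusted p = 0.529 with an estimated correlation and 0.150 without EG189, where Itgax stood at 1.42-fold and Itgam had a log2 fold change of 0.33. In libraries EG226 to EG251 the score differences of these lists were -0.30 and -0.04, against 2.00 and 1.24 in libraries EG164 to EG195. T and NK cell genes had 7 tested members, all positive, and were not called (camera adjusted p = 0.119), and this too rested on EG189, without which 4 of 7 were positive, the median went from 1.45-fold to 1.02-fold and camera had the opposite direction (adjusted p = 0.956).

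Fibroblast genes ran the other way. Of 19 members 14 were negative, with a median at 0.670 of the control level, and Dcn and Lum, matrix proteoglycans, stood at 0.445 and 0.387. Both were scarce, Dcn averaging 3.80 CPM in control and 1.68 CPM in obese libraries and Lum 0.937 and 0.353 CPM. The score was 1.47 ± 0.36 in control libraries (SD, n = 8) and 0.98 ± 0.49 in obese libraries (SD, n = 7), with an exact permutation p of 0.0457 that became 0.214 over the 41 lists and was 0.102 without EG189. In edgeR 0 members passed over the list alone, and 4 were lower and 1, Thy1, higher at unadjusted p under 0.05. Without EG189 these counts were 2 lower and 0 higher. Smooth muscle and pericyte genes had 6 of 9 members negative, Notch3 being at 0.780, and a score exact permutation p of 0.0469. Endothelial genes had 9 of 14 members negative, Vwf, the clotting factor carrier, being at 0.691. Levels within these lists were uneven. In control libraries Notch3 averaged 38.9 CPM and Cnn1 0.623 CPM of the first, and Flt1 127.5 CPM and Tek 1.37 CPM of the second. Whether the tumour cells themselves express the more abundant members was not tested, so a lower list need not mean fewer such cells. camera called all 3 lists as lower, at adjusted p of 5.87e-04, 0.0159 and 0.0430, against adjusted p = 0.306, 0.306 and 0.529 with an estimated correlation. Without EG189 the smooth muscle and endothelial lists were not called (adjusted p of 0.0572 and 0.126), but their medians moved little, from 0.760 to 0.804 and from 0.851 to 0.882 of the control level. The score difference of the smooth muscle list was -0.74 in libraries EG164 to EG195 and -0.10 in libraries EG226 to EG251 (interaction exact permutation p = 0.0690, adjusted p = 0.958). The smooth muscle list was also not called without EG167, EG175 or EG226 (up to 0.0793), nor the endothelial list without EG175, EG226, EG195 or EG251 (up to 0.150). Adipocyte, enteric glia with neuron, and mesothelium genes had 4 of 7, 2 of 5 and 3 of 6 members positive and were not called (camera adjusted p of 0.980, 0.491 and 0.414). Of the red blood cell list only Hba-a1 and Hbb-bs could be tested, at 2.05-fold and 1.46-fold, and Hba-a1 was higher over this list of 2 alone. Without EG189, where 3 members could be tested, 0 passed in edgeR over the list alone (1 at unadjusted p under 0.05).

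**Figure D3:**
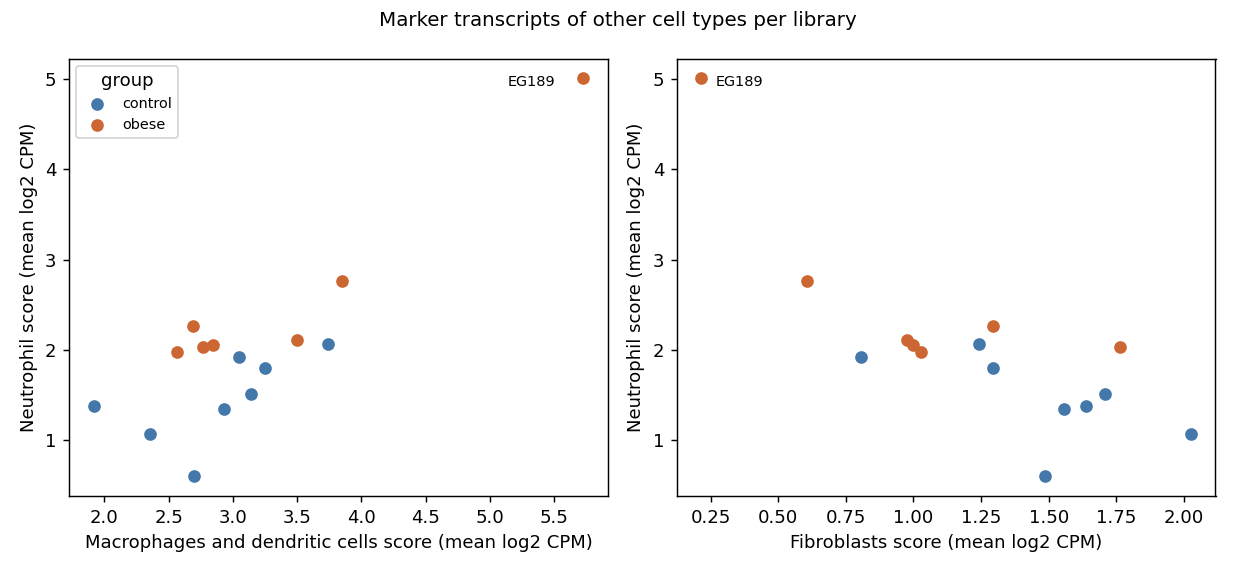
Neutrophil score (vertical axis, mean log2 CPM) against the macrophage and dendritic cell score (left) and the fibroblast score (right) in 15 libraries, coloured by group. Library EG189 stands at a neutrophil score of 5.003, and the other 6 obese libraries lie between 1.97 and 2.76.

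Stem cell and Wnt target genes had mostly negative fold changes. Of 23 members 20 were negative at a median of 0.896, and Axin2 and Rnf43, feedback inhibitors of Wnt signalling, and Tnfrsf19 stood at 0.771, 0.793 and 0.821 of the control level, with Lgr5, the stem cell receptor, at 0.838. Lef1, a Wnt effector, had a log2 fold change of 0.58 ± 0.21 (SE). In edgeR 0 members passed over the list alone, and 4 were lower and 1 higher at unadjusted p under 0.05. camera gave adjusted p = 6.21e-04 with a preset correlation and adjusted p = 0.529 with an estimated correlation, and the score difference was -0.14 (exact permutation p = 0.116, 2 of 7 obese libraries above the control median). The difference was -0.29 in libraries EG164 to EG195 and -0.02 in libraries EG226 to EG251. The fetal-like and YAP programme, epithelial-mesenchymal transition, absorptive colonocyte, goblet and deep crypt secretory, enteroendocrine and tuft lists were not called. Their camera adjusted p were 0.980, 0.180, 0.575, 0.191, 0.0734 and 0.479, and 12 of 23, 12 of 16, 13 of 20, 7 of 18, 4 of 15 and 7 of 12 members were positive. Without EG189 camera called the goblet list as lower (adjusted p = 0.00980), with 1 of 18 members positive and a median of 0.834 against 0.935 with all libraries, and the tuft list had the opposite direction, with 5 of 12 positive.

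The unfolded protein response had 15 of 21 members positive and 5 higher over the list alone, against 0 over all genes. These were Trib3 and Chac1, targets of the ATF4 branch (1.33-fold and 1.57-fold), and the chaperones Calr, Pdia4 and Hsp90b1 (1.10-fold, 1.10-fold and 1.11-fold). All 7 obese libraries scored above the control median, with a difference of 0.10 and an exact permutation p of 0.0205 that became 0.142 over the 41 lists. camera gave adjusted p = 0.00160 with a preset correlation and adjusted p = 0.306 with an estimated correlation. Without EG189 0 members passed in edgeR over the list alone (5 at unadjusted p under 0.05), but the median was 1.07-fold, as with all libraries, and camera called the list in all 15 fits without 1 library. With length and GC offset 0 members passed over the list alone too (8 at unadjusted p under 0.05), at a median of 1.07-fold. Hypoxia, dissociation and immediate early, mitochondrially encoded and p53 target genes were not called. Their camera adjusted p were 0.0734, 0.124, 0.223 and 0.245, and 14 of 19, 7 of 23, 6 of 10 and 13 of 18 members were positive.

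Across the 41 lists camera with a preset correlation of 0.01 called 20, of which 16 were higher and 4 lower. With an estimated correlation, whose median over the lists was 0.306, 0 of the 20 calls held, the smallest adjusted p being 0.306, and 3 lists had an unadjusted p under 0.05. Divisions of the 15 libraries at random into 8 and 7 gave a median of 16 such calls. With 1 library left out at a time 12 of the 20 calls held in all 15 fits, and 11 of the other 21 lists were called in at least 1 fit. Beyond those named above, these were enteroendocrine genes in 7 fits, hypoxia in 6, dissociation and immediate early genes in 5, T and NK cells in 4, goblet genes in 3 (without EG227, EG189 or EG250, as lower) and mitochondrially encoded genes in 3. Insulin and IGF signalling, MYC targets and cytosolic ribosomal proteins were called in 1 fit each, without EG235, EG189 and EG195. The directional test of fry called 0 lists, and its mixed test called 3, cholesterol synthesis, the unfolded protein response and serine, one-carbon and nucleotide synthesis. The list scores had 9 exact permutation p under 0.05, 7 higher and 2 lower, where 2.05 would be expected by chance. These scores come from the same libraries and vary together, so the count can stray far from 2.05 by chance. It was not compared with random divisions.

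The EG numbers fall into EG164 to EG195 (4 control and 3 obese libraries) and EG226 to EG251 (4 control and 4 obese), a split the labels do not call a batch. In edgeR 0 genes had an adjusted p under 0.05 for the interaction of group with this split (535 at unadjusted p under 0.05), and 0 differed between its sides (507 at unadjusted p under 0.05). Of the 20 lists called by camera 16 had a score difference of the same sign on both sides. The 4 that changed sign were fatty acid oxidation, B and plasma cells, macrophages, all given above, and glutathione and xenobiotic metabolism, at 0.36 and -0.07. Cholesterol synthesis differed by 0.26 and 0.24, DNA replication by 0.25 and 0.18, NF-kB and TNF genes by 0.40 and 0.32, and neutrophil genes by 1.70 and 0.70 in that order. No interaction of a list score with the split passed (smallest adjusted p = 0.958 by exact permutation). The exact test cannot give a p under 0.0286 on either side, so a single list cannot pass there after adjustment over 41.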

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

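The tests of EG189 as the sole cause, of the fibroblast score, of the neutrophil minus macrophage score and of all explanations for the leukocyte transcripts in EG189 were chosen only after the results were seen. In 96 measures, read in each group, the gap between the most extreme library and its nearest neighbour was divided by the range of the group, and 16 of 192 groups exceeded the 95% critical value. Chance exceeds it in about 1 of 20 groups, which would be 9.6 here.

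Obese library EG189 was far above the other 6 obese libraries in the B and plasma cell score (4.76 against at most 1.57, ratio 0.6858), the macrophage and dendritic cell score (5.73 against at most 3.85, 0.5931), the neutrophil score (5.003 against at most 2.76, 0.7395) and Ptprc (ratio 0.6405), and lowest in Cdh1 at 1451 CPM (ratio 0.6423). Its Epcam, though, was the highest of the 15 libraries at 1903.5 CPM, and its Vil1 the lowest at 326.8 CPM. The low Cdh1 therefore does not decide whether it held fewer epithelial cells. EG189 had the highest score of the 15 libraries in 4 of the 4 leukocyte lists. Its Igha stood at 1639, Lyz2 at 1282 and S100a9 at 85.7 CPM, against means of 47.3, 126 and 9.91 CPM in the other 14 libraries. Low depth is argued against, since EG195 and EG239 were shallower and scored at most 1.504 in the B and plasma list, whereas an exchange of labels with a control library cannot be told apart, because the highest control value of Ptprc, 14.52 CPM against 90.8 in EG189, would be low after an exchange too. Residual leukocytes of several types may account for these transcripts, although the cells had passed a CD45 depletion and an EpCAM enrichment. Whether more of them came through the enrichment or the tumour itself held more stays open, as does a difference due to obesity, which 1 library cannot test.

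The higher neutrophil score of the obese group did not rest on EG189 alone, since without it the difference was 0.7358 (exact permutation p = 0.00400). A lower purity that raises every other cell type alike would also raise the fibroblast score. That score differed by -0.4869 with all libraries (exact permutation p = 0.0457, 0.214 over the 41 lists). Without EG189 it differed by -0.3587 (exact permutation p = 0.102), so it does not settle this explanation. Were all leukocytes higher alike, the neutrophil minus macrophage score would not differ. Without EG189 it differed by 0.5849 (exact permutation p = 0.0253, not adjusted), and the macrophage score by 0.15 (exact permutation p = 0.615). The neutrophil list was singled out for its score in these same libraries, and this contrast was chosen afterwards. It therefore does not settle whether all leukocytes were higher alike. Expression of shared markers by the tumour cells was set against 7 members taken to be restricted to neutrophils, a choice that was not tested here. Without EG189, a library singled out after the data were seen, their score differed by 0.6692 (exact permutation p = 0.00633). Of the 7, 6 were positive and Ly6g stood at 0.958-fold, while S100a8, shared with the alarm list, stood at only 1.14-fold. The 7 belong to the same list, and their expression by tumour cells was not measured apart, so this explanation is not settled. Lower purity, more of all leukocytes alike and expression by the tumour cells thus stay open. So do a higher number of neutrophils in tumours of obese hosts, which may be the cause, and neutrophils that stick to epithelial cells through the enrichment. Chance also stays open, since the adjusted p without EG189 was 0.168 (0.0239 to 0.168 without 1 library at a time). A CD45 depletion should remove neutrophils, and S100a8 and S100a9 averaged only 5.54 and 9.91 CPM outside EG189.

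Across 10079 genes the log2 fold change fell with transcript length (Spearman rho -0.37, across genes, which are not independent replicates), from a median of 0.08 in the shortest 10% of genes to -0.10 in the longest 10%. The libraries' trends on length averaged 0.13 ± 0.28 in control (SD, n = 8) and -0.11 ± 0.33 in obese libraries (SD, n = 7; exact permutation p = 0.143). After this trend and that on GC content were removed, the differences were 0.248 for the cholesterol score (0.24 before, exact permutation p = 0.0165) and 0.2048 for the DNA replication score (0.20 before, exact permutation p = 0.0173), which argues against the trend as their whole cause, and without EG189 they were 0.2588 and 0.2026 (exact permutation p = 0.0187 and 0.0256). For the respiratory chain score the trend and a difference between the groups cannot be told apart, since the difference went from 0.14 to 0.0996 (exact permutation p = 0.0614), and without EG189 to 0.0942 (exact permutation p = 0.253), both of which left part of the difference but within the spread between libraries. A response of sterol and replication genes to host obesity may remain for the first 2 scores, as a hypothesis found and tested on the same data.

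Of the obese libraries EG251 had the highest share of unmapped reads (9.29%, 95% Wilson interval 9.28 to 9.30, ratio 0.6142), of ambiguous reads (8.83%, 8.82 to 8.84, ratio 0.8343) and of counts in its 10 most abundant genes (6.68%, 6.67 to 6.69, ratio 0.8402). These intervals cover counting error only. Among the 8 control libraries EG226 had the highest adipocyte score (3.64 against at most 3.27, ratio 0.566) and the lowest Cyp51 (96.4 CPM, ratio 0.576). Among the same 8 libraries EG164 had the highest enteric glia and neuron score (3.34 against at most 2.92, ratio 0.5807), the highest score of mitochondrially encoded transcripts (7.996 against at most 7.74, ratio 0.6192) and the highest Cplx2 (25.3 CPM, ratio 0.5269). EG235 had the lowest Ephb6 (56.2 CPM, ratio 0.5969) and the highest Trp53 (27.1 CPM, ratio 0.5376) of the control libraries, while EG189 lay beyond both values. Uty, on the Y chromosome, gave 3 counts in obese library EG250 and 0 in the other obese libraries (ratio 1.0).

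Divisions of the 15 libraries into 8 and 7, 100 in number with the real one included, were refitted in full. Chance cannot be excluded for the 1822 genes at unadjusted p under 0.05, a number reached in 6 of 100 divisions, the highest of the others being 2762. Nor can it be excluded for the 20 lists called by camera with a preset correlation, a number reached in 25 of 100 divisions, the highest of the others being 29. For the 0 genes at adjusted p under 0.05 the count of divisions, 100 of 100, is no test, since no division can give fewer, and the highest of the others was 0. That divisions made at random call a median of 16 lists points to genes that vary together between libraries, beyond what the preset correlation allows.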

How the results depend on the processing

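Leaving out EG189 and EG251 together and the offset for transcript length and GC content were chosen only after the data were seen. The count of 0 genes by edgeR became 26 with DESeq2, and the cause was not tested, while without 1 library at a time it ranged from 0 to 1 (Acot7 without EG235, Plch2 without EG250). The 1822 genes at unadjusted p under 0.05 became 3706 with no gene filter, where 32157 genes were tested, and 454 in libraries EG226 to EG251, where fewer libraries were compared. With 1 library left out they ranged from 1266 (without EG189) to 2342 (without EG235). No paired analysis was possible because the labels give no number shared between groups. The 24 genes of smallest p kept their sign in all 693 values under alternatives. They were chosen by their p in the same libraries that the alternatives refit, so this was favoured by the choice and is no separate support. The 20 lists called by camera became 0 with an estimated correlation, 0 with the directional test of fry and 3 with its mixed test, and otherwise 16 to 25. For cholesterol synthesis, DNA replication, NF-kB and neutrophil genes the adjusted p was 0.3062 each with an estimated correlation, and 0.1572, 0.1572, 0.1928 and 0.2395 with the directional test of fry. With its mixed test DNA replication, NF-kB and neutrophil genes gave 0.05607, 0.07306 and 0.192. These tests allow for correlation between genes within a list. fry also asks another question than camera, since it compares a list with no change rather than with the other genes. B and plasma cell genes had the opposite direction in libraries EG226 to EG251 (adjusted p = 0.03182) and without EG189 and EG251 (0.9931), as had macrophage genes (0.8152 and 0.8041), both settings without EG189. The 1 list called by its score became 0 with the run of EG numbers as a term, 0 without EG189 and EG251, 0 with z values and 5 with medians, and ranged from 0 to 1 without 1 library at a time, being 1 without EG235 or EG243. The cause was not tested. The values of 0 in libraries EG164 to EG195 and 0 in libraries EG226 to EG251 say nothing on stability, since a list alone cannot pass there after adjustment (smallest possible exact permutation p = 0.0286). The 5 by medians were cholesterol synthesis, DNA replication, fatty acid synthesis, epithelial alarm and neutrophil genes. The median log2 fold change of all genes with TMM, DESeq2 size factors and library size alone was 0.0083, 0.0035 and -0.0021. Depth of 19206205 to 29415264 counts limits genes near 1 CPM, such as Cxcr2 at 0.746 CPM in control libraries.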

Other observations

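The 3 lists in the next paragraph were written, and tested, only after the gene values were seen; the relations across libraries below were set out before their values were computed.

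Proteasome subunits, which make up the cell's main protease, had 31 of 31 tested members with a positive log2 fold change, at a median of 1.08-fold, and 13 were higher at unadjusted p under 0.05. Their score differed by 0.11 (exact permutation p = 0.0208, 0.0625 over these 3 lists) and by 0.06 after removal of the length and GC trend (exact permutation p = 0.0107). Mitochondrial ribosomal proteins had 31 of 32 members positive at a median of 1.08-fold, with a score difference of 0.10 (exact permutation p = 0.0668). Fragments of ribosomal RNA and genes that hold them, 7 features among them CT010467.1 and Lars2, took 3.44% of the gene counts of EG251 (95% Wilson interval 3.43 to 3.45, counting error only) and at most 0.751% in the other libraries, and their score did not pass (exact permutation p = 0.311). Obese libraries were shallower, at 22835576 against 26295208 gene counts on average (exact permutation p = 0.0134, 0.107 over 8 depth measures).

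Cholesterol synthesis and DNA replication scores moved together across the 15 libraries, with r = 0.8877 (permutation p = 2e-05, 4e-05 adjusted over 4 relations) and rho = 0.85 (permutation p = 1.80e-04). Without EG195 and EG226, the libraries farthest from the median, r was 0.76 (permutation p = 0.00244), and it was 0.83 within 8 control and 0.86 within 7 obese libraries (exact permutation p = 0.0105 and 0.0173). A hypothesis that fits is that libraries with more cells in S phase make more sterol enzymes, which may hold in both groups alike, but the order of cause is not tested here. Scores of other lists vary together too, and this r was not set against those of other pairs. The relation therefore need not be particular to sterol and replication genes.

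The length trend of a library was set against both metabolic scores. It tracked the respiratory chain score at r = -0.9432 (permutation p = 1e-05, the smallest that 100000 permutations can give, 4e-05 adjusted over 4 relations). A list of mostly short or mostly long transcripts would follow such a trend whatever its cause. The r therefore does not tell library or RNA quality from a change in these genes. The length trend gave r = -0.1387 with the cholesterol score (permutation p = 0.622, rho = -0.22 with permutation p = 0.426, r = -0.24 without EG189 and EG239, -0.39 within control and 0.47 within obese libraries). An r of this size over 15 libraries excludes neither a weak relation nor the absence of one, so a p above the threshold does not decide it.

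A relation of chemokine transcripts to neutrophil transcripts was tested without EG189, a library singled out after the data were seen. Over 14 libraries the neutrophil score and the mean log2 CPM of Cxcl1, Cxcl5 and Ccl20 had r = 0.8671 (permutation p = 1.10e-04, 1.47e-04 adjusted over 4 relations) and rho = 0.75 (permutation p = 0.00290), and r = 0.67 without EG171 and EG229 (permutation p = 0.0163). Within 8 control libraries r was 0.93 (exact permutation p = 0.00126), and within 6 obese libraries it was -0.07 (exact permutation p = 0.839), so the relation rests on the control libraries and on the difference between the groups. It may reflect chemokines that draw neutrophils in control hosts, but leukocytes can also express these chemokines, which was not tested. Nor need every member of this mean attract neutrophils, and Cxcl2 was not part of it.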
